A study of Mus musculus with 39 samples.

How the data were processed

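Bulk RNA was sequenced from 39 mouse tumours of a Braf-mutated melanoma grown in C57BL/6 animals. Per the labels' protocols, treatment began on day 7 after injection of the tumour cells, and mice received vehicle, EPAT (antagonists of the prostaglandin E2 receptors EP2 and EP4, at 30 mpk from a 3 mg/mL stock in doses of 200 µl), anti-PD-1 antibody at 200 µg per dose, or both, for 2 or 5 days. The extraction protocol in the labels speaks of tumours isolated on day 4, which matches neither time point, and the groups used here follow the time point given for each tumour. Libraries were made from 500 ng of total RNA with a QuantSeq forward kit, which counts tags near the 3' ends of polyadenylated transcripts, so a count per gene carries no gene length term and transcripts without a poly(A) tail are poorly sampled.

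The authors deposited a table of whole-number counts per Ensembl gene and a table of log2 CPM (counts scaled to a common library total). Per the submitters' processing notes, the tools used were bcl2fastq, STAR, featureCounts and limma with the mouse builds mm10 and GRCm38. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty. The count table held 39179 genes, of which 13751 had no count in any library. The deposited log2 table held 16095 genes, and its values differed from log2(count + 0.5) by one constant per library, with a largest deviation of 5e-09. Every gene kept in it exceeded 0.5 CPM in at least 4 libraries. The log2 values entered 1 alternative, and all other tests used the counts. Gene symbols and positions came from the GENCODE annotation of GRCm38 by Ensembl identifier, and 37607 of the identifiers matched, including 14912 of those tested.

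Total counts per library ranged from 8385741 to 15558113 with a median of 12193825. Gm42418, a gene overlapping ribosomal RNA sequence, took between 1.9% and 12.9% of a library's counts. No pair of libraries of a group agreed within counting noise, the lowest chi-square per gene of any pair being 10.7, so each library counted as 1 replicate. The labels do not state that the libraries of a group came from separate animals, and the p-values measure the spread between these samples.

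Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15070 genes. Library sizes were scaled by TMM. A quasi-likelihood negative binomial model with robust shrinkage was fitted to all 39 libraries with 1 mean per group, leaving 31 residual degrees of freedom, and the common biological coefficient of variation was 0.323. Every adjusted p of a gene is from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested in that comparison, 2-sided, and a gene passed when it was under 0.05. The standard error given beside a log2 fold change is the fold change divided by the square root of F. Values in CPM are TMM-scaled means with SD over the libraries of a group. There were 18 comparisons: each treatment against vehicle and the combination against each single treatment on either day, the EPAT effect averaged over tumours with and without anti-PD-1, the interaction of EPAT and anti-PD-1, vehicle between days, and each treatment effect between days.

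Gene groups were 31 lists of pathway and cell type genes. For the 10 pairwise comparisons on 1 day each list was tested with fry of limma 3.58.1 on the same model, which asks whether its genes move, on balance, one way, with adjustment over the 31 lists. Camera was run with its preset correlation between genes and with an estimated one. A list score is the mean log2 CPM of the measured members in a library. Of the 12 members of the melanocyte list only 2 were measured above the filter.

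Genes named in the text followed a rule. In each comparison against vehicle, of the combination with a single treatment, and of the averaged EPAT effect, they were the genes with adjusted p under 0.05, mean log2 CPM of at least 1 and a symbol that is not a predicted or clone name, up to 10 in each direction by fold change, whose treated libraries lay on one side of the control mean in all but at most 1 library. Where none passed, the 5 genes with the smallest unadjusted p were taken and are said not to pass. Up to 4 members of each list by smallest p were added, and Ptger2, Ptger4, Ptgs2, Pdcd1, Cd274, Ifng, Cxcl9, Cxcl10, Gzmb and Cd8a were always reported. The groups, comparisons, lists, this rule and all but 5 of the other settings tried were fixed before the data were examined.

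The pipeline was tested on simulated data made from the real means and library sizes. For the combination against vehicle on day 5, simulated with 14940 genes, 53% of genes changed 2-fold and 87% of genes changed 4-fold were called, with 4 false among 144 calls. For anti-PD-1 against vehicle on day 2 (14922 genes) these shares were 49% and 80%, with 10 false among 139 calls. For the combination on day 2 (14932 genes) they were 51% and 87%, with 2 false among 140 calls, and for EPAT on day 5 (14923 genes) 49% and 81%, with 4 false among 134 calls.

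Other settings tried were RLE scaling, no filter on low counts except leaving out genes at 0 in every library, a model of only the libraries compared, the replicate number in the title as a block, leaving out each library in turn, leaving out 3 libraries whose first title number is shared mostly with tumours of the other day, DESeq2 1.42.0, limma-trend on the deposited log2 values, camera for the lists, and for correlations of fold changes RLE scaling or only the genes with a mean log2 CPM of at least 3. Another 5 were added after the data were seen: a term for libraries with and without lung transcripts, per-library scores of the skeletal muscle, adipocyte, keratinocyte and B cell lists as covariates, leaving out libraries that stand apart in keratinocyte or B cell genes, limma-voom with sample quality weights, and the covariates together with leaving out the library with fewest T cell reads. Correlations across samples and differences of single values were tested by permutation, 2-sided and exact where stated.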

Results

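Bulk RNA was measured in 39 tumours of a Braf-mutated mouse melanoma line grown in C57BL/6 mice. The tumours fell into 8 groups: vehicle, anti-PD-1, EPAT or the combination of both, each sampled after 2 or 5 days of treatment, with 5 libraries per group and 4 for anti-PD-1 on day 2. Anti-PD-1 is an antibody that blocks an inhibitory receptor of T cells. EPAT stands for antagonists of EP2 and EP4, the receptors through which prostaglandin E2 raises cyclic AMP. The comparisons ask whether blocking this inflammatory lipid signal changes the immune content of tumours, alone or together with the antibody. Total counts per library were 8385741 to 15060936 for vehicle on day 2, 10132830 to 14296918 for anti-PD-1, 11341709 to 14893401 for EPAT and 11018946 to 13869880 for the combination. On day 5 they were 10012064 to 15558113, 9896094 to 13248170, 8895991 to 14943145 and 9177143 to 13999081 in the same order. Fold changes below are log2 values ± SE, and levels are CPM, counts scaled to a common library total, ± SD.

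The genes of the drug targets were expressed at very different levels. In vehicle tumours on day 5, Ptgs2, the inducible enzyme of prostaglandin synthesis, stood at 94.2 ± 31.6 CPM (n = 5), Ptger4, the gene for EP4, at 19.1 ± 7.58 CPM, and Ptger2, the gene for EP2, at 1.25 ± 0.72 CPM. Pdcd1, which encodes PD-1, stood at 6.76 ± 1.78 CPM and Cd274, which encodes its ligand PD-L1, at 46.6 ± 35.8 CPM. None of these genes passed the test in any treatment against vehicle. Of the melanocyte list only Mitf, the lineage transcription factor, and Sox10 were measured above the filter.

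Tumour pieces differed in tissue content. Genes of skeletal muscle such as Acta1 and Myh4 led the first principal component, which took 36.1% of the variance of the 1000 most variable genes, and the next 2 components took 14.3% and 7.8%. The skeletal muscle score averaged 1.56 ± 2.71 log2 CPM (SD) in vehicle tumours on day 2 and 5.83 ± 0.90 on day 5. Vehicle day 2 replicate 1 lay 5.02 log2 units above the median of all libraries in B and plasma cell genes, and vehicle day 2 replicate 2 lay 4.41 above it in keratinocyte genes, as did combination day 5 replicate 3 by 3.78. A group of 23 libraries carried reads of the lung genes Sftpc, Sftpa1 and Scgb1a1 while 16 held almost none. Libraries with lung transcripts numbered 3 of 5 for vehicle, 4 of 4 for anti-PD-1, 4 of 5 for EPAT and 3 of 5 for the combination on day 2, and 3, 2, 2 and 2 of 5 on day 5. For some of the gene groups described below, the difference in score within libraries with and without lung transcripts is given.

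**Figure D1:**
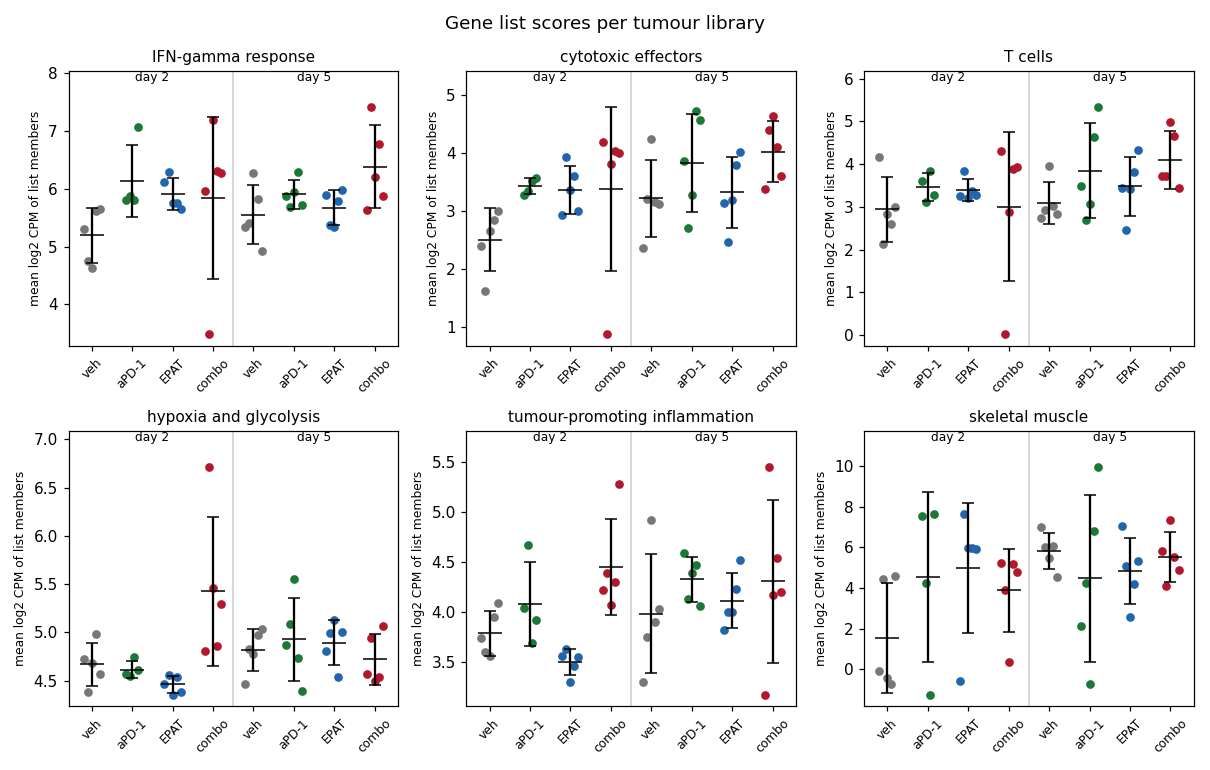
Scores of 6 gene lists in each tumour library, as the mean log2 CPM of the measured members (vertical axis), by treatment group and day (horizontal axis). Points are libraries, horizontal marks are group means and bars are SD. The hypoxia score of the combination on day 2 averaged 5.43 ± 0.77 against 4.46 ± 0.09 for EPAT, and the T cell score of combination day 2 replicate 2 lies at 0.02.

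After 2 days of anti-PD-1, genes of inflammatory monocytes and of interferon signalling were higher in the treated tumours than in vehicle tumours. All 10 measured monocyte genes were higher, with a mean log2 fold change of 1.02. They included Ccr2, the receptor that draws monocytes from blood (1.18 ± 0.32), Plac8 (1.49 ± 0.43), Ifitm6 (1.42 ± 0.46) and Chil3 (1.54 ± 0.52). All 20 genes of the interferon-γ response were higher, mean 1.02, among them the GTPases Tgtp1 (1.98 ± 0.67) and Tgtp2 (1.56 ± 0.58). Replicate 5 stood apart in this list, with a score of 7.075 against 5.804 to 5.879 in the other treated tumours and 5.194 ± 0.477 in vehicle. Of 8 genes of MHC class II presentation 7 were higher, led by the protease Ctss (0.82 ± 0.27) and H2-DMa (0.97 ± 0.34). Prf1, the pore-forming protein of killer cells, was at 1.43 ± 0.44 and Batf3, a factor of cross-presenting dendritic cells, at 1.26 ± 0.35.

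None of these anti-PD-1 differences passed over all genes. edgeR called 0 of 15070 genes, with a smallest adjusted p of 0.524 and 1073 genes at an unadjusted p under 0.05, of which 651 were higher and 422 lower. DESeq2 called 2 genes, limma-trend 0 and limma-voom with quality weights 4. Adjusted over the list alone, 6 monocyte genes, 6 genes of the interferon-γ response and 6 of MHC class II passed, against 0 of each over all genes. The monocyte list had a fry adjusted p of 0.0586, which was 0.0136 without anti-PD-1 day 2 replicate 2 and ranged up to 0.336 over the other left-out libraries. With an estimated correlation its adjusted p was 0.0682. The 5 genes with the smallest p were the transcription factor gene Creb5 (0.96 ± 0.22), the kininogen gene Kng2 (2.92 ± 0.66), Glycam1 (-7.73 ± 1.78), Cd200r4 (1.55 ± 0.37) and Gpr141 (1.49 ± 0.36), all not passing. Glycam1, made by lymph node venules, averaged 105 ± 234 CPM in vehicle tumours and 0.49 ± 0.41 CPM under anti-PD-1. Vehicle replicate 1 alone carried it, with 6962 counts of Glycam1 against 2 to 8 in the other 4 vehicle libraries, so its fold changes on day 2 rest on that library.

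Other tissues moved along with these groups on day 2. Against vehicle, all 12 muscle genes were higher under anti-PD-1, mean 3.48, with 10 passing adjusted over the list alone and 0 over all genes. All 7 keratinocyte genes were lower, mean -3.85 (5 adjusted over the list alone), as were all 5 B and plasma cell genes, mean -2.79 (4 adjusted over the list alone). The B and plasma cell difference rested on vehicle replicate 1, with a score of 5.545. The other vehicle tumours scored -0.1559 to 0.5259 and the anti-PD-1 tumours -0.1844 to 1.703. In keratinocyte genes vehicle replicate 2 stood highest, with a score of 3.663 against -0.7118 to 1.141 in the other vehicle tumours. The anti-PD-1 tumours scored -1.108 to -0.3557. All 4 treated libraries carried lung transcripts, so only a difference against the 3 vehicle libraries with them can be had. It was 1.10 for the monocyte score and 0.92 for the interferon-γ score.

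After 2 days of EPAT alone, interferon, antigen presentation and monocyte genes were higher than in vehicle tumours. All 22 genes of the type I interferon response were higher, mean 0.85, among them the RNA-sensing enzyme Oas2 (1.10 ± 0.34), the master regulator Irf7 (1.11 ± 0.37) and Cmpk2 (1.09 ± 0.41). All 20 interferon-γ genes were higher, mean 0.69, and 7 of 8 MHC class II genes, with H2-DMb1 at 0.81 ± 0.26 and the invariant chain gene Cd74 at 0.82 ± 0.33. Ccl4, a chemokine for lymphocytes, was at 1.21 ± 0.37, B2m, the light chain of MHC class I, at 0.68 ± 0.21 and Tbx21, the master factor of type 1 lymphocytes, at 1.57 ± 0.52. Of the monocyte genes 7 of 10 were higher, with Ccr2 at 1.15 ± 0.31 and Ms4a4c at 1.23 ± 0.38, and Batf3 was at 1.29 ± 0.33.

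For EPAT on day 2, edgeR called 0 genes, with a smallest adjusted p of 0.338 and 939 genes at an unadjusted p under 0.05 (503 higher, 436 lower), while DESeq2 called 1 and limma-trend and limma-voom 0 each. Adjusted over the list alone, 6 genes of MHC class II, 3 of monocytes and 0 of the type I interferon response passed, against 0 of each over all genes. The smallest fry adjusted p was 0.188. The 5 genes with the smallest p, none passing, were Glycam1 (-7.96 ± 1.62), the B cell gene Ms4a1 (-5.73 ± 1.28), the junction protein gene Jup (-1.33 ± 0.31), the B cell adaptor gene Bank1 (-2.53 ± 0.63) and the keratin gene Krt10 (-1.80 ± 0.46). Ms4a1 averaged 19.2 ± 42.4 CPM in vehicle tumours, where replicate 1 held the B cell signal. All 12 muscle genes were higher, mean 3.09, and all 7 keratinocyte and all 5 B and plasma cell genes were lower, means -3.60 and -3.32. Vehicle replicate 2 had the highest keratinocyte score, 3.663 against at most 1.141 in the other vehicle tumours. The type I interferon score differed by 0.81 within libraries with lung transcripts and by 1.19 within those without.

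The combination for 2 days brought no gene past the threshold, but several lay close to it. The 5 named by the rule each had an edgeR adjusted p of 0.0562, a value that other genes such as Xdh (1.36) shared. Mt2, a metal-binding stress protein, stood at 1897 ± 718 CPM against 781 ± 134 CPM in vehicle (1.28 ± 0.25), F10, coagulation factor X, at 26.1 ± 2.79 against 5.77 ± 3.25 (2.17 ± 0.43) and Ndrg1, a gene induced by low oxygen, at 185 ± 121 against 81.4 ± 10.4 (1.18 ± 0.24). The phosphofructokinase gene Pfkp was at 1.00 ± 0.21 and Glycam1, carried by vehicle replicate 1, at -8.03 ± 1.63. All 15 genes of hypoxia and glycolysis were higher, mean 0.99, among them the hexokinase gene Hk2 (1.21 ± 0.28), the oxidase gene Ero1l (1.88 ± 0.43) and the carbonic anhydrase gene Car9 (2.11 ± 0.56). All 16 genes of tumour-promoting inflammation were higher, mean 0.87, led by the neutrophil chemokine gene Cxcl2 (2.35 ± 0.66), the nitric oxide synthase gene Nos2 (2.25 ± 0.72) and the arginase gene Arg1 (2.27 ± 0.80).

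Immune effector genes were higher under the combination on day 2 too. All 20 interferon-γ genes were higher, mean 1.01, with Cd274 at 1.67 ± 0.46 (91.6 ± 75.4 CPM against 28.8 ± 12.6). All 16 genes of MHC class I were higher, mean 0.71, with B2m at 0.77 ± 0.21 and the peptide transporter gene Tap1 at 1.05 ± 0.29. All 14 cytotoxic genes were higher, mean 1.16, with the granzyme genes Gzmb at 1.78 ± 0.55 and Gzma at 1.77 ± 0.67. Adjusted over the list alone, 12 genes of the interferon-γ response, 11 of type I interferon, 8 of hypoxia, 7 of MHC class I, 7 of MHC class II, 6 cytotoxic genes, 5 type 1 chemokines and 3 of tumour-promoting inflammation passed, against 0 of each over all genes. Batf3 was at 1.55 ± 0.33, and the cytokine antagonist gene Il18bp at 1.58 ± 0.43. Of the 20 cell cycle genes 19 were lower, mean -0.32. Adipocyte genes were lower in all 8, mean -3.35, with 8 passing adjusted over the list alone. All 5 B and plasma cell genes (mean -3.46) and 6 of 7 keratinocyte genes (mean -3.30) were lower too. Vehicle replicates 1 and 3 carried the adipocyte genes, with scores of 6.304 and 3.946 against -1.488 to 2.336 in the other vehicle tumours. The combination tumours scored -0.1946 to 1.809. Vehicle replicate 1 also carried the B and plasma cell genes, with a score of 5.545 against at most 0.5259 in the other vehicle tumours. In keratinocyte genes vehicle replicate 2 stood highest, at 3.663 against at most 1.141. All 12 muscle genes were higher, mean 1.36.

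For the combination on day 2, edgeR called 0 genes, with 1541 at an unadjusted p under 0.05 (955 higher, 586 lower), while DESeq2 called 81, limma-trend 1 and limma-voom with quality weights 580. No list passed, the smallest fry adjusted p being 0.0789 for hypoxia (adjusted p = 0.155 with an estimated correlation). The counts depended on the model and on single libraries. A model of only the libraries compared called 99 genes (92 higher, 7 lower). Without combination day 2 replicate 2 edgeR called 20 genes, all higher, among them B2m, Tap1, Batf3, Ccl4, Il18bp and Cd274 (1.95, adjusted p = 0.045), and 12 lists passed, led by the interferon-γ list (mean 1.30, adjusted p = 0.00333, and 0.0202 as adjusted p with an estimated correlation). With an estimated correlation 10 of the 12 passed in that fit, and hypoxia and checkpoint receptors did not (adjusted p = 0.075 each). Without it the mean of the hypoxia list was 0.48. Leaving out replicate 1 gave 2 genes and 1 list, and leaving out replicate 4 gave 3 genes and 1 list. Within libraries with lung transcripts the scores differed by 0.96 for interferon-γ, 1.79 for cytotoxic genes, 1.07 for T cells and 0.29 for hypoxia, and within those without by 0.19, -0.49, -1.46 and 1.46.

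On day 5, anti-PD-1 tumours had higher T cell genes on average. All 17 T cell genes were higher than in vehicle, mean 1.03, among them the adhesion receptor genes Cd2 (1.18 ± 0.44) and Cd6 (1.49 ± 0.62). Cd8a, the co-receptor of killer T cells, stood at 39.5 ± 34.6 CPM against 18.7 ± 8.72 CPM, and Pdcd1 at 17.4 ± 14.7 against 6.76 ± 1.78 (1.37 ± 0.50). All 10 checkpoint receptor genes were higher, mean 0.74, and all 12 fibroblast genes, mean 0.75, with Col1a1 at 0.93 ± 0.46. Of the 20 cell cycle genes 19 were lower, mean -0.27, with the thymidylate synthase gene Tyms at -0.42 ± 0.16 and the cyclin gene Ccnb1 at -0.57 ± 0.23.

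None of this passed a test. edgeR called 0 genes for anti-PD-1 on day 5, with a smallest adjusted p of 0.645 and 1077 genes at an unadjusted p under 0.05 (689 higher, 388 lower), while DESeq2 called 1 and limma-trend and limma-voom 0 each. Adjusted over the list alone, 0 genes of the T cell, checkpoint, fibroblast and cell cycle lists passed, as over all genes, and the fry adjusted p was 0.51 for each of these lists. The T cell score was above the vehicle mean in 3 of 5 treated tumours and the fibroblast score in 2, replicates 4 and 5. Without replicate 5 the mean fold change was 0.51 for T cell, 0.40 for checkpoint and -0.14 for cell cycle genes, and without replicate 4 it was 0.29 for fibroblast genes. The 5 genes with the smallest p, none passing, were the kinetochore gene Spc24 (-0.68 ± 0.17), Lurap1l (-0.88 ± 0.22), Det1 (-0.57 ± 0.15), the lipid carrier gene Apod (1.34 ± 0.38) and the DNA repair gene Fancf (-0.75 ± 0.21). The T cell score differed by 0.80 within libraries with lung transcripts and by 0.52 within those without, and all 12 muscle genes were higher by fitted fold change, mean 1.75, while the muscle score of the group was lower (4.48 ± 4.12 against 5.83 ± 0.90) and the direction of the fry test was down.

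After 5 days of EPAT alone a few regulators stood apart without passing. The immediate early gene Egr1 stood at 242 ± 47.8 CPM against 97.7 ± 15.8 CPM in vehicle (1.31 ± 0.25), its relative Egr2 at 14.1 ± 2.42 against 5.81 ± 1.63 (1.27 ± 0.26) and the clock repressor gene Cry1 at 17.5 ± 1.96 against 28.2 ± 3.82 (-0.69 ± 0.14). Their adjusted p was 0.118 each, and all 5 treated libraries lay on the same side of the vehicle mean for each gene. Next by p were Ccdc28a (0.58 ± 0.15) and the deacetylase gene Hdac4 (-0.52 ± 0.14). Of 16 cyclic AMP and CREB target genes 14 were higher, mean 0.29, with the clock gene Per1 at 0.44 ± 0.22 and the nuclear receptor genes Nr4a1 at 0.96 ± 0.53 and Nr4a2 at 0.61 ± 0.33. All 8 mitochondrially encoded genes were higher, mean 0.24. All 17 T cell genes were higher, mean 0.45 (fry adjusted p = 0.914). Interferon-γ genes were split, 10 higher and 10 lower, mean 0.04, as were the macrophage genes at 7 and 7, mean 0.02, where the direction of the fry test was down.

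For EPAT on day 5, edgeR called 0 genes, with 256 at an unadjusted p under 0.05 (100 higher, 156 lower), while DESeq2 and limma-voom called 3 each and limma-trend 0. No list passed, the smallest fry adjusted p being 0.443 for the mitochondrial and the adipocyte lists (0.0932 and 0.0747 as adjusted p with an estimated correlation). Adjusted over the list alone, 0 genes of the cyclic AMP and 0 of the mitochondrial list passed, as over all genes. All 8 adipocyte genes were lower, mean -2.94, with Lep at -3.81 ± 1.39 and Adipoq at -3.51 ± 1.28, and 6 passed adjusted over the list alone. The cyclic AMP score differed by 0.45 within libraries with lung transcripts and by 0.13 within those without, and the adipocyte score by -2.50 and -2.56.

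After 5 days of the combination, 4 genes passed and all 4 fell against vehicle, each lower in 5 of 5 tumours. Rdh10, an enzyme that makes retinal for retinoic acid synthesis, fell from 131 ± 20.6 to 53.4 ± 24.8 CPM (n = 5 each), a log2 fold change of -1.29 ± 0.23 with an edgeR adjusted p of 0.0148. Fkbp5, a co-chaperone of steroid receptors that glucocorticoids induce, fell from 57.0 ± 12.9 to 25.1 ± 5.61 CPM (-1.18 ± 0.21, adjusted p = 0.0148). Tmem198b, a gene for a membrane protein, fell from 20.1 ± 3.12 to 10.9 ± 1.96 CPM (-0.88 ± 0.17) and Got1, the cytosolic aspartate aminotransferase, from 89.5 ± 21.4 to 52.1 ± 15.2 CPM (-0.78 ± 0.15), with an adjusted p of 0.0341 each. Within libraries with lung transcripts (2 against 3) Rdh10, Fkbp5, Tmem198b and Got1 differed by -1.77, -1.23, -0.996 and -0.594 in mean log2 CPM. Within those without (3 against 2) they differed by -1.02, -0.98, -0.71 and -0.88. Host tissue scores averaged higher in the combination tumours than in vehicle. They were 7.98 ± 0.326 against 7.415 ± 0.641 for fibroblasts, 7.31 ± 0.335 against 6.785 ± 0.295 for macrophages and 4.14 ± 0.318 against 3.84 ± 0.514 for endothelium. No model took these 3 scores into account, so a difference in tissue share is not separated from the treatment. On GRCm38, Rdh10 (ENSMUSG00000025921) lies on chromosome 1 from 16105774 to 16133734, Fkbp5 (ENSMUSG00000024222) on chromosome 17 from 28399094 to 28517527, Tmem198b (ENSMUSG00000047090) on chromosome 10 from 128800036 to 128804370 and Got1 (ENSMUSG00000025190) on chromosome 19 from 43499752 to 43524605.

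**Figure D2:**
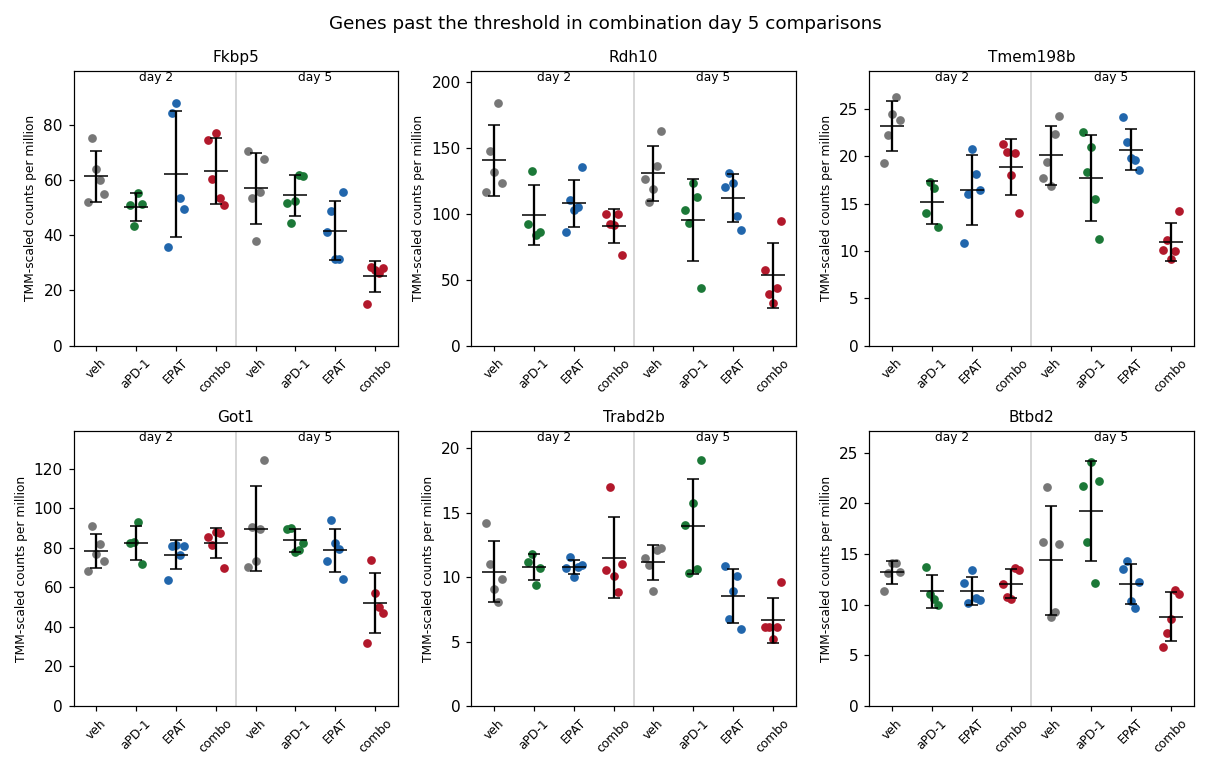
TMM-scaled CPM (vertical axis) of the 6 genes that passed in comparisons of day 5 combination tumours, by treatment group and day (horizontal axis). Points are libraries, horizontal marks are group means and bars are SD. Fkbp5 averaged 25.1 ± 5.61 in combination tumours on day 5 and 57.0 ± 12.9 in vehicle tumours.

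These counts depended on which libraries were kept. When 1 library was left out at a time, the count ran from 0 to 205. It was 0 without combination replicate 1, 3 or 4 or without vehicle replicate 1, 4 or 5, 2 without vehicle replicate 2, 7 without combination replicate 5 and 205 (114 higher, 91 lower) without vehicle replicate 3. The fold change of Fkbp5 stayed between -1.30 and -1.04 in these fits. Without vehicle replicate 3 the genes that passed included Pkib, an inhibitor of the cyclic AMP dependent kinase (1.72, adjusted p = 0.0184), the membrane scaffold gene Stom (0.82, adjusted p = 0.0242) and Slamf7, a receptor of killer cells and macrophages (1.82). Over all alternatives the adjusted p of Rdh10 and of Fkbp5 ran from 0.00011 to 0.306, that of Tmem198b from 0.000992 to 0.306 and that of Got1 from 0.00106 to 0.307. DESeq2 called 78 genes, limma-trend 6, limma-voom 4 and edgeR on the libraries of this comparison alone 0. With scores of other tissues as covariates, a setting chosen after the data were seen, edgeR called 264 genes (140 higher, 124 lower) and fry 1 list. With the library poorest in T cells also left out they called 665 genes (408 higher, 257 lower) and 13 lists. That library is combination day 2 replicate 2, outside this comparison, so it acts here only through the parts of the model that all libraries share. In the fit to all libraries 2485 genes had an unadjusted p under 0.05 (1086 higher, 1399 lower).

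Immune genes were higher in combination tumours on day 5, without passing over all genes. All 17 T cell genes were higher, mean 1.10, with Cd2 at 1.34 ± 0.44 and the costimulator gene Icos at 1.17 ± 0.47. All 22 type I interferon genes were higher, mean 0.83, with the RNA sensor gene Ddx58 at 0.89 ± 0.25 and the antiviral genes Rsad2 at 1.15 ± 0.39 and Mx2 at 1.08 ± 0.39. All 20 interferon-γ genes were higher, mean 0.96, with Tgtp2 at 1.64 ± 0.55 and Cd274 at 1.24 ± 0.45 (110 ± 34.6 against 46.6 ± 35.8 CPM). All 12 type 1 chemokine genes were higher, mean 0.86, with Cxcl11 at 1.44 ± 0.44 and Ccl8 at 1.13 ± 0.39. Fos, of the cyclic AMP and CREB list, was at 1.18 ± 0.33, while the score of that list was lower (4.89 ± 0.279 against 5.053 ± 0.212). All 14 macrophage genes were higher, mean 0.56, with the efferocytosis receptor gene Mertk at 0.60 ± 0.19, and all 7 regulatory T cell genes, mean 0.77, with Foxp3 at 1.06 ± 0.50. All 9 heat shock genes were lower, mean -0.39, with Hspa1b at -1.14 ± 0.41, and 19 of 20 cell cycle genes, mean -0.34.

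Adjusted over the list alone, 13 type I interferon genes, 2 type 1 chemokines, 2 cyclic AMP targets and 0 of the interferon-γ, T cell, macrophage and heat shock lists passed, against 0 of each over all genes. No list passed fry, the smallest adjusted p being 0.0924 for heat shock and 0.136 for the interferon and T cell lists, and with an estimated correlation the adjusted p was 0.355 for each of them. Without vehicle replicate 3, 12 lists passed, among them heat shock (0.0152) and interferon-γ, cytotoxic, macrophage and cell cycle genes (0.0495 each), but with an estimated correlation none of the 12 passed in that fit (adjusted p = 0.299 each). In vehicle replicate 3 the T cell score was 3.95, against 3.02 in the next highest vehicle tumour. Within libraries with lung transcripts the interferon-γ score differed by 1.74 and the T cell score by 1.32, and within those without by 0.07 and 0.60. All 8 adipocyte genes were lower, mean -1.89, and 5 of 7 keratinocyte genes were higher, mean 3.10 (4 adjusted over the list alone), while 1 of 5 tumours, replicate 3, had a keratinocyte score above the vehicle mean.

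The always-reported genes did not pass in any treatment. Ptger2 was at 1.09 ± 0.49 under anti-PD-1, 0.75 ± 0.47 under EPAT and 1.47 ± 0.47 under the combination on day 2, and at 1.14 ± 0.46, -0.23 ± 0.47 and 0.30 ± 0.47 on day 5. Ptger4 was at 0.80 ± 0.31 under the combination on day 5 and between 0.09 and 0.41 in the other 5 comparisons. Ptgs2 lay between -0.45 and 0.42 in all 6. Under EPAT on day 5 Ptgs2 stood at 320 CPM in replicate 2. The other EPAT tumours of that day, at 60.4 to 88.95 CPM, lay below the vehicle mean of 94.2 CPM. Ifng, the gene of interferon-γ, was at 1.68 ± 0.65 under the combination on day 2 and at 0.94 ± 0.62 on day 5, Cxcl9 at 0.70 ± 0.44 and 0.30 ± 0.44, and Cxcl10 at 0.88 ± 0.50 and 1.17 ± 0.50. Gzmb was at 0.80 ± 0.54 and Cd8a at 1.09 ± 0.59 under the combination on day 5. Several of these differences under the combination had opposite signs within libraries with and without lung transcripts, in mean log2 CPM. For Ifng they were 2.16 and -0.796 on day 2 and 2.10 and -0.436 on day 5. For Cxcl9, Cxcl10 and Cd8a on day 2 they were 0.95 and -1.05, 0.799 and -0.292, and 1.25 and -2.73. For Gzmb they were 2.24 and -0.225 on day 2 and 1.71 and -0.651 on day 5. Libraries without lung transcripts numbered 2 against 2 on day 2 and 3 against 2 on day 5. Those of day 2 included combination replicate 2, poorest in T cell reads (Ifng at 0 CPM). Combination replicate 3, the other one, lay above both vehicle libraries in Ifng, Cxcl9, Cxcl10 and Gzmb and between them in Cd8a. Those of day 5 included vehicle replicate 3, highest of its group in Ifng and Gzmb (13.7 and 39.6 CPM).

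Set against EPAT alone, the combination on day 2 had higher genes of hypoxia and of tumour-promoting inflammation, and both lists passed fry, the second of them not with an estimated correlation. All 15 hypoxia genes were higher, mean 1.22, with Ndrg1 at 1.26 ± 0.24, the vasoactive peptide gene Adm at 2.51 ± 0.52, Ero1l at 1.95 ± 0.43 and Hk2 at 1.22 ± 0.28. The fry adjusted p was 0.013 (adjusted p = 0.0128 with an estimated correlation), all 5 tumours lay above the EPAT mean, and 12 genes passed adjusted over the list alone and 0 over all genes. All 16 genes of tumour-promoting inflammation were higher, mean 1.17 and median 0.86, with Cxcl2 at 3.04 ± 0.68, Nos2 at 2.78 ± 0.74, Arg1 at 2.69 ± 0.81 and the cytokine gene Lif at 1.84 ± 0.71. That list had a fry adjusted p of 0.0421 (adjusted p = 0.0547 with an estimated correlation), with 3 genes passing adjusted over the list alone. Cx3cr1, a receptor of resident macrophages, was at -1.27 ± 0.31, while the score of the macrophage list was higher (7.124 ± 0.193 against 6.882 ± 0.232).

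The hypoxia list passed in each of the 10 fits that left out 1 library, with an adjusted p from 0.00282 to 0.0407, but its mean was 0.69 without combination day 2 replicate 2. The inflammation list passed in 3 of the 10 fits and had an adjusted p from 0.0357 to 0.195. It did not pass without combination replicate 2 or 5 or without any 1 of the 5 EPAT libraries. Within libraries with lung transcripts the hypoxia score differed by 0.55 and the inflammation score by 1.09, and within those without (2 against 1 library) by 1.54 and 0.77. Muscle genes were lower in all 12, mean -1.72, and adipocyte genes in all 8, mean -1.41. edgeR called 0 genes, with a smallest adjusted p of 0.104 (Ndrg1) and 1109 at an unadjusted p under 0.05, while DESeq2 called 19, limma-trend 0 and limma-voom with quality weights 155. Without combination replicate 1, 3 or 4 or EPAT replicate 1 the count was 1. After Ndrg1, the genes with the smallest p were Adm, Mt2 (1.11), Ero1l and the chemokine gene Cxcl14 (-1.44), none passing.

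Against anti-PD-1 alone on day 2, all 15 hypoxia genes were higher in the combination as well, mean 1.05, with Adm at 2.15 ± 0.56, Ndrg1 at 1.02 ± 0.26 and the glucose transporter gene Slc2a1 at 1.18 ± 0.36. The list did not pass (adjusted p = 0.106, and 0.052 as adjusted p with an estimated correlation), although 10 genes passed adjusted over the list alone and 0 over all genes. Without combination replicate 1 or replicate 4 it passed, with a lowest adjusted p of 0.0252, and without replicate 2 its mean was 0.51. The hypoxia score differed by 0.37 within libraries with lung transcripts. Cxcl2 was at 2.20 ± 0.71, and interferon-γ genes were split, 11 higher and 9 lower, with a mean of -0.01, a median of 0.10 and a fry test pointing down. Adipocyte genes were lower in all 8, mean -2.56 (5 adjusted over the list alone). edgeR called 0 genes, with a smallest adjusted p of 0.925 and 656 at an unadjusted p under 0.05, DESeq2 and limma-trend 0 each and limma-voom with quality weights 703. Without anti-PD-1 replicate 2 edgeR called 1. The 5 genes with the smallest p, none passing, were Cxcl14 (-1.48), the topoisomerase gene Top3a (-0.72), Ndrg1, the kinase gene Map3k20 (-0.57) and Adm.

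Against anti-PD-1 alone on day 5, 3 genes passed and all 3 were lower in the combination, each with an edgeR adjusted p of 0.0256. Fkbp5 stood at 25.1 ± 5.61 CPM against 54.3 ± 7.34 CPM under anti-PD-1 (-1.11 ± 0.21). Btbd2, a gene for a BTB domain protein, stood at 8.82 ± 2.40 against 19.2 ± 4.96 CPM (-1.12 ± 0.21). Trabd2b, which encodes an inhibitor of Wnt proteins, stood at 6.64 ± 1.73 against 13.9 ± 3.68 CPM (-1.07 ± 0.20). In vehicle tumours on day 5 Btbd2 stood at 14.4 ± 5.35 and Trabd2b at 11.1 ± 1.36 CPM, below the anti-PD-1 means. Neither of them passed in the combination against vehicle. Within libraries with lung transcripts Fkbp5, Btbd2 and Trabd2b differed by -0.94, -0.61 and -0.75 in mean log2 CPM, and within those without by -1.27, -1.44 and -1.24. Btbd2 (ENSMUSG00000003344) lies on chromosome 10 from 80642617 to 80657071 and Trabd2b (ENSMUSG00000070867) on chromosome 4 from 114406724 to 114615098. Of the 16 cyclic AMP and CREB targets 12 were lower, mean -0.35, with Per1 at -1.04 ± 0.22 and Fosl2 at -0.52 ± 0.17, while Fos was at 0.99 ± 0.33. Of these, 5 passed adjusted over the list alone and 0 over all genes, and the list had a fry adjusted p of 0.273. Tgtp1 was at 1.88 ± 0.64 and Cxcl11 at 1.42 ± 0.44, and all 22 type I interferon genes were higher, mean 0.45 (fry adjusted p = 0.985).

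The count of 3 ran from 0 to 6 when 1 library was left out. It was 0 without anti-PD-1 replicate 1, 3 or 5 or combination replicate 1 or 3, 1 without combination replicate 2, 5 without combination replicate 4 and 6 without anti-PD-1 replicate 2. Over all alternatives the adjusted p ran from 0.000625 to 0.57 for Fkbp5, from 0.000551 to 1 for Trabd2b and likewise for Btbd2. DESeq2 called 18 genes, limma-trend 4 and limma-voom with quality weights 32, and 951 genes had an unadjusted p under 0.05 (219 higher, 732 lower). The cyclic AMP score differed by -0.02 within libraries with lung transcripts and by -0.52 within those without. All 12 muscle genes were lower by fitted fold change, mean -1.83, while the muscle score was higher by 1.06 and the fry test pointed up. The keratin gene Krt14 was at 5.88 ± 1.61, and only combination replicate 3 had a keratinocyte score above the anti-PD-1 mean.

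Set against EPAT alone on day 5, the combination had lower cyclic AMP and CREB targets and higher interferon genes, and no gene passed. Of 16 targets 12 were lower, mean -0.43, with Fosl2 at -0.81 ± 0.17, Nr4a1 at -2.42 ± 0.56, Nr4a2 at -1.42 ± 0.34 and Per1 at -0.95 ± 0.22, and 6 passed adjusted over the list alone and 0 over all genes. The fry adjusted p for a common direction was 0.0619 and for change in either direction 0.0396, and it was 0.319 as adjusted p with an estimated correlation. Without combination replicate 4 the adjusted p for a common direction was 0.0321, and 1 list passed without that library or without EPAT replicate 4. All 22 type I interferon genes were higher, mean 0.93, with Oas2 at 1.21 ± 0.34 and Mx2 at 1.23 ± 0.39, and 14 passed adjusted over the list alone (fry adjusted p = 0.164). All 20 interferon-γ genes were higher, mean 0.92, with Tgtp1 at 2.19 ± 0.65, and 2 passed adjusted over the list alone. Of 8 mitochondrially encoded genes 6 were lower, mean -0.22, with mt-Nd1 at -0.54 ± 0.14.

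In that comparison edgeR called 0 genes, with a smallest adjusted p of 0.0663 and 1917 at an unadjusted p under 0.05 (820 higher, 1097 lower), while DESeq2 called 24, limma-trend 0 and limma-voom 3. Without combination replicate 5 the count was 4 and without replicate 4 it was 1. The 5 genes with the smallest p were Tmem198b (-0.92, adjusted p = 0.0663), Stom (0.82, adjusted p = 0.0666), Rdh10 (-1.07), Fosl2 and N4bp1 (0.57), the last 3 with an adjusted p of 0.131. The interferon-γ score differed by 1.74 within libraries with lung transcripts and by 0.02 within those without, and the cyclic AMP score by -0.28 and -0.60. Adipocyte genes were higher in all 8, mean 1.05, and 6 of 7 keratinocyte genes, mean 4.00 (3 adjusted over the list alone), while 2 of 5 tumours had a keratinocyte score above the EPAT mean and replicate 3 alone stood far above it, at 3.03.

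Averaged over tumours with and without anti-PD-1, 2 genes were lower with EPAT on day 5, each with an edgeR adjusted p of 0.0468. Fkbp5 fell from 55.7 ± 9.97 to 33.4 ± 11.8 CPM (-0.78 ± 0.15, below the control mean of log2 values in 9 of 10 treated tumours) and Trabd2b from 12.5 ± 3.00 to 7.58 ± 2.07 CPM (-0.73 ± 0.14, below it in 10 of 10). The larger part came from the combination against anti-PD-1, with Fkbp5 at 25.1 against 54.3 CPM and Trabd2b at 6.64 against 13.95 CPM. EPAT alone stood at 41.6 against 57.0 and at 8.52 against 11.1 CPM in vehicle, where neither gene passed. For EPAT alone they differed by -0.715 and -0.612 in mean log2 CPM within libraries with lung transcripts, and by -0.115 and -0.18 within those without. With a term for lung transcripts neither gene passed in the averaged test, although the fold changes barely moved (Fkbp5 -0.77 and Trabd2b -0.74, edgeR adjusted p = 0.0571 each). Of the 20 fits that left out 1 library, 17 lost calls: the count was 1 without combination replicate 5 or EPAT replicate 5, 2 without anti-PD-1 replicate 2 or 4, 3 without vehicle replicate 3 and 0 without any other. Over all alternatives the adjusted p ran from 0.00216 to 0.326 for Fkbp5 and from 0.00216 to 0.935 for Trabd2b. DESeq2 called 5 genes, limma-trend 2 and limma-voom with quality weights 131, with 625 at an unadjusted p under 0.05. On day 2 edgeR, DESeq2, limma-trend and limma-voom called 0 genes, with 521 at an unadjusted p under 0.05. The smallest p there were those of Bank1 (-1.69), Armcx4 (-0.45), Ms4a1 (-3.33), the triglyceride enzyme gene Dgat2 (-1.77) and the prolactin receptor gene Prlr (-3.41), with an adjusted p of 0.998.

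Whether EPAT acted differently with and without anti-PD-1 was tested as an interaction. No gene passed on either day by edgeR, with 1097 genes on day 2 and 467 on day 5 at an unadjusted p under 0.05, and DESeq2 called 2 and 0, limma-trend 0 and 0 and limma-voom 45 and 0. Leaving out anti-PD-1 replicate 2 on day 2 or vehicle replicate 5 on day 5 gave 1 gene. All 15 hypoxia genes had a positive interaction on day 2, mean 1.28, with 9 passing adjusted over the list alone (fry adjusted p = 0.182), and all 12 muscle genes a negative one, mean -5.20. On day 5, 15 of 16 cyclic AMP and CREB targets had a negative interaction, mean -0.64, with a fry adjusted p of 0.0516 and 0.0258 as adjusted p with an estimated correlation, and 4 passed adjusted over the list alone.

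Between days, vehicle tumours differed in mitochondrially encoded genes. Of 8 measured genes 7 were lower on day 5, mean -0.52, with a fry adjusted p of 0.0217 (adjusted p = 0.0172 with an estimated correlation) and 2 passing adjusted over the list alone. This list test was not run with a library left out. Day 5 replicate 5 scored lowest, at 8.18 against 8.699 to 8.912 in the other day 5 vehicle tumours. As a share of all counts, mitochondrially encoded genes took 7.68% to 10.6% on day 2 and 4% to 11.7% on day 5. All 12 muscle genes were higher on day 5, mean 2.85, and 6 of 7 keratinocyte genes were lower, mean -3.74. Day 2 replicate 2 had a keratinocyte score of 3.663, against at most 1.141 in the other day 2 vehicle tumours. edgeR called 0 genes between vehicle days, with 828 at an unadjusted p under 0.05, DESeq2 9, limma-trend 1 and limma-voom 0. The treatment effects were also compared between days: edgeR and limma-trend called 0 genes for anti-PD-1, EPAT and the combination, with 503, 786 and 528 genes at an unadjusted p under 0.05, DESeq2 2, 4 and 4 and limma-voom 0, 22 and 0. Without EPAT day 2 replicate 4 or vehicle day 2 replicate 2 the EPAT effect gave 1 gene.

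Across 15070 genes, which are not independent replicates, the fold changes of the combination on day 2 and day 5 correlated with r = 0.437 and rho = 0.45. Among 100 random regroupings of the libraries r lay between -0.308 and 0.473, for a permutation p of 0.02 and 0.1 after adjustment over 5 such correlations. The other 4 were -0.21 and 0.0716 for EPAT with against without anti-PD-1 on days 2 and 5, 0.122 for anti-PD-1 between days and -0.188 for EPAT between days, with adjusted permutation p values of 0.45, 0.73, 0.73 and 0.45. Without vehicle day 5 replicate 5 the correlation of EPAT between days was -0.304, with a permutation p of 0.04.

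The remaining lists did not pass for the combination against vehicle on day 5. Their means were -0.02 for the prostaglandin E2 pathway (median -0.26, 8 of 13 lower), 0.02 for mitochondrially encoded genes (median -0.03 and a fry test pointing down), 0.29 for MHC class I, 0.50 for MHC class II, 0.74 for checkpoint receptors, 0.54 for monocytes, 0.46 for fibroblasts, -0.05 for hypoxia, 0.38 for tumour-promoting inflammation, -0.08 for muscle, -0.20 for B and plasma cells, 0.40 for NF-κB targets, 0.54 for NK cells, 0.54 for type 1 dendritic cells, 0.41 for activated dendritic cells, 0.24 for neutrophils, 0.26 for endothelium, 1.03 for the 2 melanocyte genes and -0.09 for erythroid cells. For the cytotoxic effector list the score is given, 4.027 ± 0.531 against 3.219 ± 0.671 in vehicle. That of the cyclic AMP and CREB targets was 4.89 ± 0.279 against 5.053 ± 0.212. Camera with its preset correlation called between 3 and 20 lists in each of the 10 comparisons, and with an estimated correlation only hypoxia in the combination against EPAT on day 2 held.

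**Figure D3:**
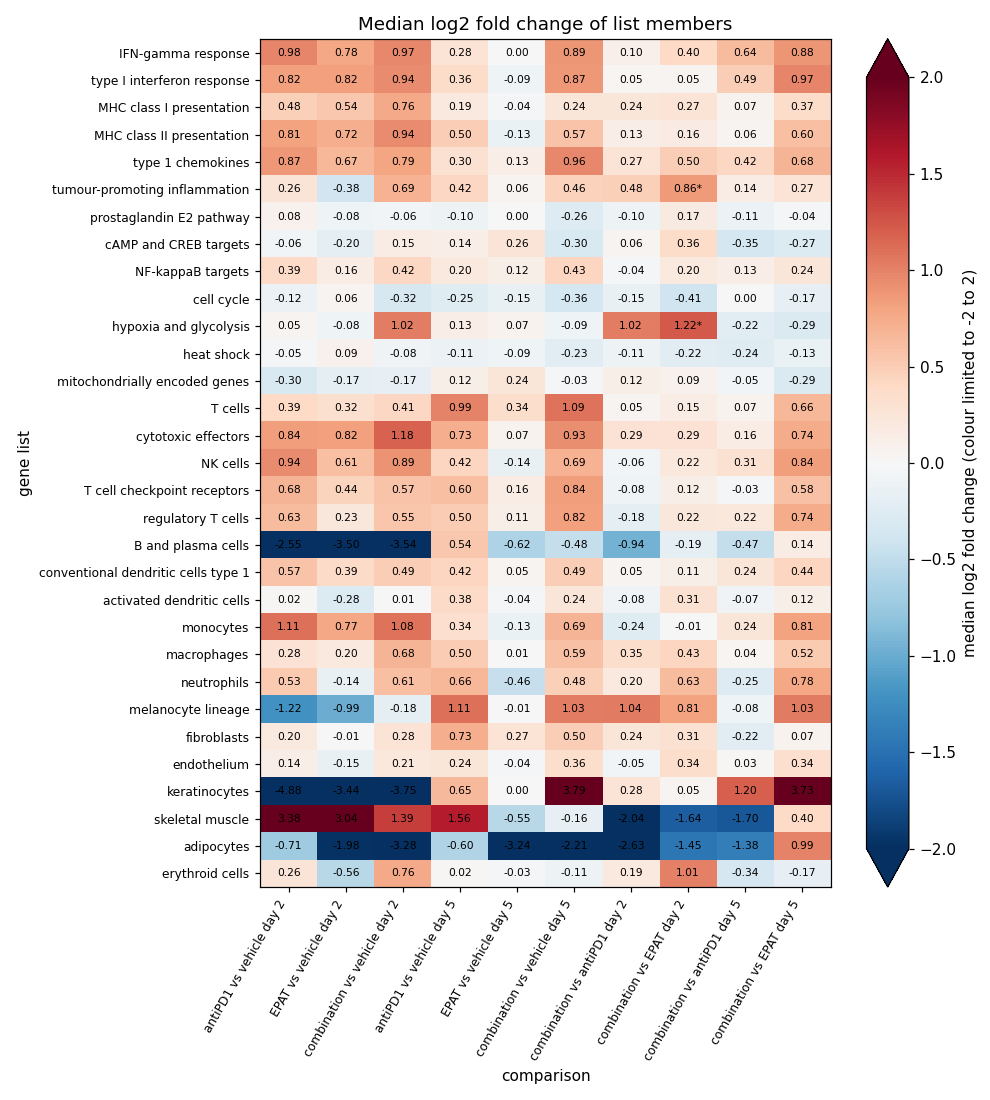
Median log2 fold change of the measured members of 31 gene lists (vertical axis) in 10 comparisons (horizontal axis). Colour and number give the median, and a star marks a fry adjusted p under 0.05. The hypoxia list has the star in the combination against EPAT on day 2, with a median of 1.22.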

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

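The tests of explanations in this part were chosen after the result was seen, except that of the mean of 13 further glucocorticoid-induced genes.

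A library stood apart from the rest of its group in 37 of the 384 groups of values examined, each a list score or a gene in 1 treatment group, where chance picks out about 1 in 20, or 19.2. The number given for each is the gap to the nearest library of the group divided by the range of the group. The measures overlap in the cells they count, so they are not independent of each other. Several fell on the same library, combination day 2 replicate 2, which lay lowest in its group for MHC class II (0.775), type 1 chemokines (0.887), NF-κB targets (0.789), cell cycle (0.79), cytotoxic effectors (0.886), NK cells (0.781), type 1 dendritic cells (0.89), Ifng (0.817), Cxcl9 (0.766), Gzmb (0.892) and Cd8a (0.821). Vehicle day 5 replicate 3 lay highest in NF-κB targets (0.806), T cells (0.767), checkpoint receptors (0.848), type 1 dendritic cells (0.912) and macrophages (0.725). Anti-PD-1 day 2 replicate 5 lay highest in the interferon-γ response (0.941) and in Cd274 (0.908).

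Other libraries stood apart in 1 or 2 measures each. On day 2 they were vehicle replicate 2, low in MHC class I (0.725) and Ptger4 (0.724), vehicle replicate 1, high in B and plasma cells (0.88), combination replicate 5, high in tumour-promoting inflammation (0.73) and low in Rdh10 (0.769), combination replicate 1, high in heat shock genes (0.912), and combination replicate 3, low in muscle (0.723). Among EPAT tumours on day 2, replicate 2 was high in T cells (0.719) and Cxcl9 (0.71), replicate 1 low in muscle (0.787) and Got1 (0.751), and replicate 3 low in Ptger4 (0.75). On day 5, combination replicate 3 was high in MHC class II (0.73) and keratinocytes (0.825), combination replicate 1 low in mitochondrially encoded genes (0.727) and Fkbp5 (0.865), combination replicate 5 high in Trabd2b (0.727), EPAT replicate 2 high in Ptgs2 (0.768) and anti-PD-1 replicate 5 low in Rdh10 (0.725).

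For 2 lists every EPAT library lay on one side of the vehicle mean on day 2 and on the other on day 5. The cyclic AMP and CREB score differed from vehicle by -0.185 on day 2 and by 0.312 on day 5, and the mitochondrial score by -0.262 and by 0.275. The mitochondrial score of EPAT tumours was alike on both days (8.914 ± 0.113 and 8.955 ± 0.117). It was the vehicle score that fell, from 9.176 ± 0.203 to 8.68 ± 0.291, the difference between vehicle days given above. The cyclic AMP score was 5.07 and 5.05 in vehicle tumours and 4.885 and 5.364 under EPAT. Without vehicle day 5 replicate 5 the mean fold change of the mitochondrial list on day 5 was 0.16, against 0.24 with it. On day 2 it was -0.15 without vehicle replicate 3, against -0.27, and that of the cyclic AMP list was -0.08 without vehicle replicate 2, against -0.18. These were picked by sign alone. The difference between days itself was tested with fry and did not pass, with an adjusted p of 0.305 and of 0.158.

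In combination day 2 replicate 2 the T cell score differed from the median of the other libraries by -3.40 log2 units, with 1 count of Cd8a, 9 of Cd3e and 0 of Ifng, and its hypoxia score lay 1.97 above theirs. Low depth is argued against by a total of 11018946 counts, since other libraries held as few as 8385741, and a lack of host cells of every type by fibroblast, macrophage and endothelium scores 1.09, 0.28 and 0.295 above the median of the others (mean 0.555). A hypoxic piece of tumour with few T cells is a hypothesis that may explain it. Over the other 38 libraries the hypoxia and T cell scores had r = -0.202 (permutation p = 0.224, and 0.224 adjusted over 2 correlations) and rho = -0.141 (permutation p = 0.398), with r = -0.124 without the 2 farthest libraries, 0.00482 in the 23 with lung transcripts and -0.482 in 15 without (permutation p = 0.0639), and no other library had so high a hypoxia score, so this stays open. A treatment effect in this tumour and a mislabelled tube were not tested.

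Fkbp5 was lower in combination tumours on day 5 (-1.18 ± 0.21), with differences of -1.23 within libraries with lung transcripts and -0.985 within those without. For a shift in the time of day of collection, a clock index of 8 genes differed by -0.00147 (SE 0.316, exact p = 1). Times on either side of the peak of such an index can give the same value, so it cannot decide this. Per1, Per2 and Cry1, outside the index, were at -0.50, -0.81 and -0.40 (edgeR adjusted p = 0.267, 0.225 and 0.197). Muscle, fat, skin or B cell content is argued against by a fold change of -1.233 with these scores as covariates (edgeR adjusted p = 0.0186, between 0.00011 and 0.306 over all alternatives). Lower glucocorticoid signalling might explain it: Fkbp5, Tsc22d3, Per1, Klf9 and Per2, already seen to be low, differed from the other 3 groups of day 5 by a mean of -0.813 (exact p = 6.45e-05, the smallest that 15504 arrangements can give), which shows nothing beyond how they were picked. Another 13 glucocorticoid-induced genes, whose mean had not been computed before although some of them, such as Mt2 and Nfkbia, were tested elsewhere, differed from vehicle by a mean of -0.0572 (exact p = 0.667), which leaves this open. An action of the drugs on Fkbp5 itself was not tested.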

How the results depend on the processing

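Of the settings below, the term for lung transcripts, the tissue scores as covariates with and without leaving out the library poorest in T cells, leaving out the libraries apart in keratinocyte or B cell genes, and limma-voom with quality weights were chosen after seeing the data. All but the lung term give very different counts in some comparisons. Unless a cause is named, the cause of a changed count was not tested.

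Among the reported genes, the lists of the 10 pairwise comparisons and the correlations, none past its threshold was reversed in direction by a setting it was run under. The lists between days and for the interaction were run only with fry and camera on all libraries. What moved was the number of genes or lists that passed. With RLE scaling the counts of 17 of the 18 gene comparisons stayed within 1.5 times the count given, the exception being the combination against EPAT on day 5 with 2 genes. With the lung term this held for 17 too, the exception being the averaged EPAT effect on day 5 with 0, where the fold change of Fkbp5 was -0.77 against -0.78 (adjusted p = 0.0571). The 5 correlations of fold changes stayed within their spread under RLE scaling and with only the genes of higher expression.

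Counts by tool differed more. DESeq2 called 2, 1 and 81 genes for anti-PD-1, EPAT and the combination on day 2 and 1, 3 and 78 on day 5. It called 19 for the combination against EPAT on day 2, 18 against anti-PD-1 and 24 against EPAT on day 5, 5 for the averaged EPAT effect on day 5, 2 for the interaction on day 2, 9 for vehicle between days and 2, 4 and 4 for the anti-PD-1, EPAT and combination effects between days. limma-trend gave 1 for the combination on day 2 and 1 for vehicle between days. limma-voom with quality weights gave 4 for anti-PD-1 and 580 for the combination on day 2, 3 for EPAT on day 5, 703 for the combination against anti-PD-1 and 155 against EPAT on day 2, 32 and 3 on day 5, 131 for the averaged EPAT effect on day 5, 45 for the interaction on day 2 and 22 for the EPAT effect between days.

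The model of only the libraries compared estimates the spread from fewer samples. It gave 99 genes for the combination on day 2, 1 for EPAT and 0 for the combination on day 5, 1 for the combination against EPAT on day 2, 0 against anti-PD-1 on day 5, 0 for the averaged EPAT effect on day 5, 3 for vehicle between days and 1 for the EPAT effect between days. With no filter more genes are tested, and the counts on day 5 were 2 for the combination, 0 against anti-PD-1 and 0 for the averaged EPAT effect. Without the 3 libraries with shared title numbers these were 2, 0 and 1. Without the libraries apart in keratinocyte or B cell genes they were 0, 0 and 0, with 1 gene for the EPAT effect between days and 1 list for the combination against EPAT on day 2. In these settings the fold change of Fkbp5 under the combination on day 5 lay between -1.22 and -1.16.

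With the tissue scores as covariates the combination on day 5 gave 264 genes (140 higher, 124 lower) and 1 list, the averaged EPAT effect on day 5 4 genes, and the combination against EPAT 1 list on day 2 and 1 on day 5. The library poorest in T cells, combination day 2 replicate 2, was then left out as well. It is in no day 5 comparison and acts there only through the parts of the model that all libraries share. The combination on day 5 then gave 665 genes (408 higher, 257 lower) and 13 lists, and the combination on day 2 12 lists. Against anti-PD-1 and EPAT on day 5 the combination gave 5 genes and 1 gene, and the averaged EPAT effect on day 5 gave 5. Against EPAT the combination gave 1 list on day 2 and 1 on day 5.

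The replicate block gave 0 genes for the combination against anti-PD-1 on day 5, 0 for the averaged EPAT effect on day 5 and 1 list for the combination against EPAT on day 2. The numbers do not pair the libraries: libraries with the same number had a mean correlation of residuals of 0.0192 (-0.557 to 0.575) against -0.00466 for different numbers, and 8 of 39 libraries matched best with one of their own number.

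Leaving out 1 library at a time gave 0 to 205 genes for the combination and 0 to 4 against EPAT on day 5, 0 to 6 against anti-PD-1, 0 to 3 for the averaged EPAT effect, 0 to 20 for the combination on day 2, and 0 to 1 for the combination against anti-PD-1 and against EPAT on day 2, for the interaction on either day and for the EPAT effect between days. The 205 included all 4 genes that passed with every library. For lists the ranges were 0 to 1 for anti-PD-1 and 0 to 12 for the combination on day 2, 0 to 12 for the combination on day 5, 0 to 1 for the combination against anti-PD-1 and 1 to 2 against EPAT on day 2, and 0 to 1 against EPAT on day 5. The correlation of EPAT fold changes between days ran from -0.304 to -0.0784, with a permutation p of 0.04 at its lowest, without vehicle day 5 replicate 5.

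Camera with its preset correlation called 18, 17 and 20 lists for anti-PD-1, EPAT and the combination on day 2, 14, 7 and 18 on day 5, 3 and 9 for the combination against anti-PD-1 and EPAT on day 2 and 4 and 19 on day 5. The preset assumes nearly independent genes, while the estimated correlation for the interferon-γ list was 0.667. With an estimated correlation the combination against EPAT on day 2 gave 1 list.

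The simulations called 49% to 53% of genes changed 2-fold and 80% to 87% of genes changed 4-fold. Each of them changed 100 genes 2-fold and 100 genes 4-fold at once, and drew the genes independently. With fewer changed genes the adjustment is stricter, so these shares do not give the chance of calling a single changed gene. Depth was not varied.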

Other observations

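The tests of lung transcripts and of Xist in this part were chosen after the result was seen, and the regroupings of libraries before.

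Pigment genes were almost silent in these tumours. In vehicle tumours on day 5, Mlana and Tyr were at 0 CPM, Dct at 0.051 and Pmel at 0.172 CPM, and Sox10 at 0.139 CPM, while Mitf stood at 42.9 ± 8.28 CPM (n = 5).

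The samples of each comparison were regrouped at random, with 60 groupings including the real one. Against EPAT on day 2 no other grouping of the combination libraries gave a list, against 2 in the real one. That share, 1 of 60, is the smallest there can be and was not adjusted over the counts regrouped, so chance is not taken as excluded. Of the 2 lists, tumour-promoting inflammation did not pass with an estimated correlation (adjusted p = 0.0547 by camera of limma) and did not pass in 7 of the 10 fits that left out 1 library. For the averaged EPAT effect on day 5, 2 of 60 gave as many genes as the 2 of the real one, a share under 0.05 without adjustment over the counts regrouped, but the highest other gave 638, so chance is not taken as excluded. Chance cannot be excluded for the combination on day 5, where 3 of 60 gave at least 4 genes and the highest other 575, or against anti-PD-1 on day 5, where 6 of 60 gave at least 3 genes and the highest other 2814. The grouping with 575 genes exchanges only combination replicate 2 and vehicle replicate 3, so it still follows the treatments in 8 of 10 libraries. It set 4 libraries with lung transcripts of 5 against 1 of 5 and differed in the fibroblast score by -0.95. The grouping with 2814 mixes the treatments and points to a structure of the samples. It set 3 of 5 against 1 of 5 and differed by 1.01 in the fibroblast and 3.47 in the muscle score. With a term for lung transcripts the real groupings of these 2 comparisons gave 4 and 3 genes.

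Where the real count was 0, all 60 of 60 groupings reach it, which says nothing about chance. The highest count of genes in another grouping was 24 for anti-PD-1, 1 for EPAT and 92 for the combination on day 2, and 2752 for anti-PD-1 and 358 for EPAT on day 5. The grouping with 92 exchanges only combination replicate 2 and vehicle replicate 5 and follows the treatments in 8 of 10 libraries. Those with 2752 and 358 mix the treatments and point to a structure of the samples: the grouping with 2752 differed by -1.32 in the fibroblast and -2.81 in the muscle score, and that with 358 by 1.12 in the fibroblast score. It was 1 and 0 for the combination against anti-PD-1 and EPAT on day 2, 2 against EPAT on day 5, 3 for the averaged EPAT effect on day 2, 98 and 513 for the interaction on days 2 and 5, 1 for vehicle between days, and 123, 0 and 1086 for the anti-PD-1, EPAT and combination effects between days. For lists the highest was 1, 0 and 14 on day 2 and 12, 3 and 9 on day 5 for anti-PD-1, EPAT and the combination, 4 against anti-PD-1 on day 2, and 18 and 3 against anti-PD-1 and EPAT on day 5.

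Lung transcripts were present in 23 libraries, with 577 to 1391 reads of Sftpc, Sftpa1 and Scgb1a1 together, and nearly absent from 16, with at most 13. Pieces of lung in some tumours are argued against by the even level, with an SD of 0.387 log2 units among the libraries that hold them. In the same libraries the SD was 2.71 for the muscle, 1.92 for the adipocyte, 1.03 for the keratinocyte and 1.21 for the B cell score. The measures are not alike, since these scores also cover libraries that hold little of the tissue. Treatment as the cause is argued against by vehicle, EPAT and combination groups that hold libraries of both kinds on both days (shares between treatments, permutation p = 0.971). Along the sample number at the end of the titles the libraries switch between having and lacking lung transcripts 3 times, where random orders gave a median of 19 (permutation p = 1e-05, the smallest possible), so RNA or reads that entered in blocks of preparation or sequencing are a candidate explanation. Which step it was is open, since the labels give no batches. No other biological explanation was tested.

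Xist, expressed in female cells, stood between 214 and 723 CPM in 38 libraries, in which the Y-linked gene Ddx3y did not exceed 0.232 CPM. In anti-PD-1 day 2 replicate 1 Xist stood at 1.61 and Ddx3y at 9.16 CPM. Among the 38, Xist may follow the share of host cells in the piece: it correlated with the mean of the fibroblast, macrophage and endothelium scores with r = 0.853 (permutation p = 1e-05, the smallest possible, and 2e-05 adjusted over 2 correlations) and rho = 0.777. Without the 2 farthest libraries r was 0.795, and it was 0.75 and 0.942 within libraries with and without lung transcripts. With all 39 libraries r was 0.311 (permutation p = 0.0618) and rho 0.732. The sexes of the mice and of the tumour line are not given in the sources used here.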
